A study of Mus musculus with 12 samples.

How the data were processed

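Bulk RNA sequencing of the hypothalamus of male C57BL/6 mice gave 12 libraries. Per the labels' protocols, RNA was extracted with Trizol and had an integrity number above 7 in every sample. Libraries were made with a stranded poly-A kit and sequenced on an Illumina NovaSeq instrument as paired reads of 150 bases. The values are raw read counts per gene, deposited by the authors as 1 table of the whole series. Per the submitters' processing notes, FastQC and featureCounts were used with the GRCm39 mouse genome. The aligner, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Genes that share sequence with pseudogenes or paralogs, such as ribosomal protein and globin genes, are therefore uncertain, as are overlapping and antisense genes.

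The table held 78334 Ensembl gene IDs. A GENCODE M21 annotation on GRCm38 and a table of RefSeq synonyms supplied names, transcript lengths and GC content only, and no coordinates are given because the builds differ. A symbol was found for 51486 IDs, or 65.7%, which carried 97.8% of the counts. No column of the table was left unused. Each library's column was matched to its sample by the library name in the labels. Library totals ran from 12950017 to 30271706 counts. Chi-square tests of each pair of libraries gave at least 22.4 per degree of freedom, so no pair looked like 1 library deposited as 2.

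Groups were taken from the sample titles: control (n = 3), diabetes (n = 4), diabetes with curcumin (n = 3) and diabetes with aged garlic extract (n = 2). The labels number the libraries within a group without saying that each came from a separate animal, so p-values measure the spread between these libraries, which may be partly technical. No batch or litter is given. Genes were filtered with filterByExpr by group, which left 25562, and scaled by TMM. All 12 libraries were fitted in 1 model with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3), and 6 contrasts were tested. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05 and no minimum fold. Standard errors are those of the log2 fold changes from that model, and levels are CPM, counts relative to TMM-scaled library size, as mean ± SD over libraries. The common dispersion was 0.653, a biological coefficient of variation of 0.808.

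31 gene lists, fixed from textbook knowledge, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, two-sided), adjusted over the 31 lists of a comparison. They covered hypothalamic peptides and transcription factors, insulin and leptin signalling, glial, vascular, choroid plexus, meningeal, pituitary, blood and neighbouring brain region markers, and mitochondrial, ribosomal, stress, clock, lipid, glucose, inflammatory, interferon and synaptic genes. A list's median log2 fold change is over group means of log2 CPM, and beside it the median of the list's edgeR log2 changes is given where that differs in sign or by over 1.5 times. Those changes depend on the prior count where a group is at 0, and are no bound; with such genes at their bound, the medians over group means given beside them stayed as they are. Its score in a library is the median over members of the deviation of log2 CPM from the gene's own mean. Another list held sex-linked genes as a check of the labels. The groups compared, the tests, the lists and the rule for naming genes were chosen before the data were examined.

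The rule for naming genes took, per main comparison, the 8 largest rises and 8 largest falls among genes that passed the test, averaged at least 1 CPM, had a proper symbol and did not overlap between groups. Where fewer than 10 genes passed, it took the 10 of smallest p among genes that averaged at least 1 CPM and had a proper symbol, so that pseudogenes and unnamed models were left out. It added up to 4 passing members and 2 others per list, and 16 genes of appetite, insulin and inflammation. For the other comparisons it took the 3 largest rises and 3 largest falls that passed, and as none passed there, the 3 of smallest p in each direction, with the same genes left out, were taken in their place. Some genes that this rule names are not reported here. A fold against a group with a count of 0 in every library is a lower bound set at 3 counts over the group. Such bounds and counting intervals (95%, exact Poisson) cover counting error only.

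Correlations across genes between contrasts that share the diabetes libraries were set beside 20 simulations of unchanged groups and beside the diabetes libraries split 2 and 2. Counts were also simulated, each gene independently, with 200 changed genes, 50 per fold size, drawn only from genes that averaged at least 1 CPM. For diabetes against control the test recovered 16, 52, 84 and 92% of changes of 2, 4, 8 and 16 fold, over 23479 genes. The shares were 12, 54, 72 and 84% for curcumin against diabetes over 23617 genes and 4, 38, 66 and 80% for garlic against diabetes over 23487 genes. They do not cover changes in genes of lower level. The alternatives were DESeq2 1.42.0, limma-voom with library weights, RLE scaling, other filters, robust spread, fits of only the compared groups, a replicate block, leaving out each library, for lists an estimated correlation and fry, and for correlations prior count 5 and Spearman's rho. Chosen after the data were seen were leaving out 2 doubted libraries (curcumin replicate 2 and diabetes replicate 4), a length and GC correction per library (lowess, span 0.3), a covariate for the number of genes detected, and rank-based camera. Where 1 garlic library was left out, the lone one was assumed to vary like the other groups. 80 regroupings of the libraries were refitted. Coverage by annotation was 85.6% of tested genes for length and GC. Tnf, Il1b and Il6 lay below the filter and were not tested.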

Results

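The hypothalamus, the brain region that controls appetite and energy use, was profiled in mice made diabetic early in life. Pups received 1 injection of streptozotocin (70 mg/kg), a toxin of insulin-producing beta cells, on postnatal day 2, and ate a high-fat diet (60% of energy) for 8 weeks from 3 weeks of age. Treated groups were gavaged daily for 28 days with curcumin (50 mg/kg), a polyphenol of turmeric, or aged garlic extract (200 mg/kg). Control and diabetes groups received the vehicle. Streptozotocin and the high-fat diet are given for the diabetes and treated groups, and neither is given for control. A comparison with control therefore cannot separate the injection from the diet. The protocol starts treatment at week 7 of the diet, whereas the design text starts it after 11 weeks, longer than the stated diet, so the timing is unresolved. Total counts were 23470800, 17575625 and 20868779 in control replicates 1 to 3 and 30271706, 17425419, 12950017 and 19882234 in diabetes replicates 1 to 4. They were 20790431, 21539173 and 18735948 in curcumin replicates 1 to 3 and 21952253 and 18332013 in garlic replicates 1 and 2. The number of genes expected at the lowest depth differed by group: 25766 to 33157 in control, 20133 to 22515 in diabetes, 20917 to 29126 in curcumin and 33125 to 34719 in garlic. The Y-linked gene Ddx3y had at least 469 counts in every library and Xist at most 32, and all mice were labelled male.

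**Figure D1:**
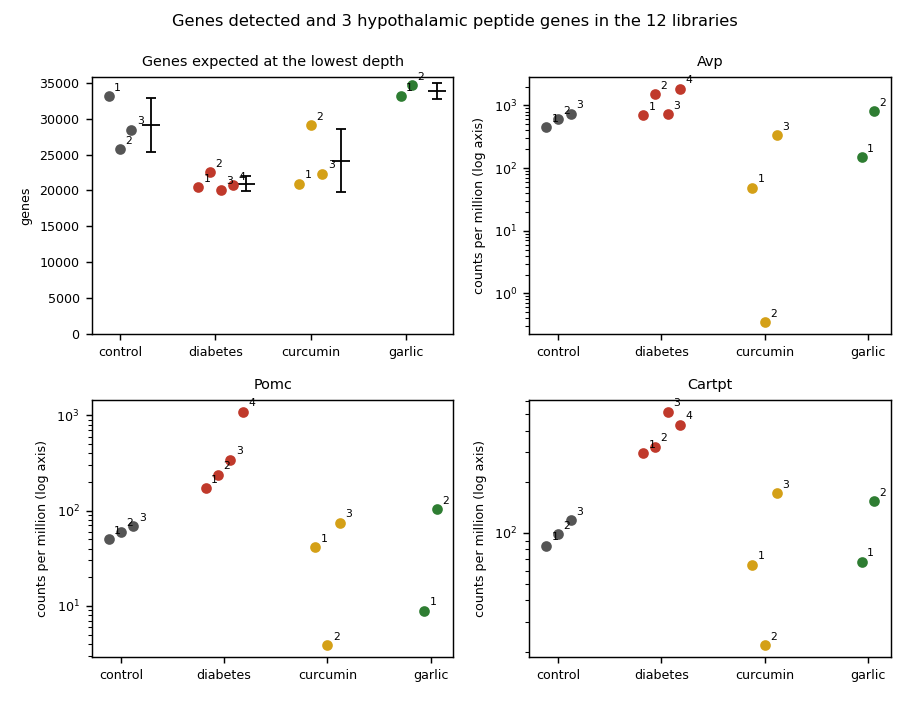
Genes expected at the lowest depth, and CPM of Avp, Pomc and Cartpt on a log axis, with 1 point per library in each group. The diabetes libraries lie at 20133 to 22515 genes, below every control library.

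The comparison of diabetes with control asked which hypothalamic genes differed in the diabetes model. By edgeR, 4 genes rose and 0 fell, with 1913 lower at an unadjusted p under 0.05 and 217 called lower by DESeq2 and 453 by limma-voom. Junb (ENSMUSG00000052837), a subunit of the AP-1 transcription factor that responds to cell stimulation, rose by 1.99 ± 0.30 on the log2 scale (87.9 ± 19.8 against 22.2 ± 1.98 CPM, n = 4 and 3, adjusted p = 0.0325). Rps2, a protein of the small ribosomal subunit, rose by 1.53 ± 0.23 (186 ± 31.1 against 64.7 ± 5.45 CPM, adjusted p = 0.0325), and S100a1, a calcium-binding protein, by 1.82 ± 0.28 (154 ± 33.4 against 43.7 ± 10.2 CPM, adjusted p = 0.0325). The other was the pseudogene Rpl34-ps1 (log2 change 1.49 ± 0.24, adjusted p = 0.0460), named after its values were seen. All 4 were higher in every diabetes library than in every control library, and none of the 4 passed with any 1 of the 7 libraries left out: edgeR then called 0 genes without control replicate 1, 2 or 3 or diabetes replicate 1, 2 or 3 (1903 to 3757 at an unadjusted p under 0.05) and 1 other gene without diabetes replicate 4.

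With pseudogenes and unnamed models left out, the genes of smallest p that did not pass were Ly6h, Ramp1, Timm8b, Nenf, Rps4l and Ndufs8 at higher levels and Necab1, a neuronal calcium-binding protein, at a log2 change of -1.54 ± 0.29, each with an adjusted p of 0.0791. The pseudogenes Rpl35a-ps6 and Rps10-ps2, named after their values were seen, had smaller p values than these, with adjusted p values of 0.0513 and 0.0791. Ly6h, a membrane-anchored neuronal protein, stood at 1364 ± 582 against 487 ± 28.4 CPM. Among the appetite genes, Pomc, the precursor of melanocortins that curb feeding, was at 460.2 ± 425 against 59.8 ± 9.22 CPM (log2 change 2.94 ± 0.83, adjusted p = 0.201). Its levels were 171, 238, 343 and 1089 CPM in diabetes replicates 1 to 4, of which replicate 4 also held Gh, the growth hormone of the pituitary, where Pomc is expressed too, at 732 CPM, and without that library the log2 change of Pomc was 2.07. Cartpt, a satiety peptide, had a log2 change of 1.97 ± 0.47 (adjusted p = 0.135). Of 38 members of that list, 0 passed over all genes and 2, Pomc and Cartpt, rose adjusted over the list alone. Agrp, a peptide that drives feeding, had 0 counts in all 4 diabetes libraries, at least 23.1-fold lower than control (adjusted p = 0.317), or at least 8.39-fold without control replicate 2. Its control levels were low, at 0.338, 2.05 and 0.317 CPM in replicates 1 to 3, where 3 counts stand at 0.128 to 0.171 CPM. The low genes Nos2, Nlrp3, Isg15 and Tal1 had 0 counts in all 4 diabetes libraries too. Npy (log2 change -0.10 ± 0.60), Lepr (-0.16 ± 0.74) and Gfap (0.26 ± 0.34) had adjusted p values of 0.994, 0.992 and 0.920, and Insr, the insulin receptor, had a log2 change of -0.56 ± 0.27 (adjusted p = 0.407). Without control replicate 3 the log2 changes of Npy and Gfap turned, to 0.88 and -0.14.

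Several gene groups stood higher in diabetes by camera. Nuclear-encoded subunits of oxidative phosphorylation had a median log2 change of 0.74 over 75 members (adjusted p = 1.11e-25, and adjusted p = 0.437 with an estimated correlation). 0 passed over all genes and 30 rose adjusted over the list alone, among them Ndufs8 (212 ± 52.9 against 77.4 ± 15.8 CPM). Ribosomal protein genes had a median of 0.51 over 79 members (adjusted p = 3.17e-16, and adjusted p = 0.437 with an estimated correlation), of which 1, Rps2, rose over all genes and 24 adjusted over the list alone. Immediate early genes, which respond within minutes to neuronal activity, had a median of 0.85 over 25 (adjusted p = 5.73e-10, and adjusted p = 0.0836 with an estimated correlation); Junb rose over all genes and 4 members, with Fos and Egr1 among them, adjusted over the list alone. Fos stood at 72.2 ± 22.0 against 23.3 ± 7.16 CPM. Glucocorticoid-induced genes had a median of 0.57 (adjusted p = 1.62e-05, and adjusted p = 0.437 with an estimated correlation), and 2, Cebpd and Mt1, rose adjusted over the list alone, with 0 over all genes. Without control replicate 3 that median was 0.22, without control replicate 1 it was 0.99 and without diabetes replicate 2 0.88.

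Thalamus and habenula markers had a median of -1.05 (adjusted p = 1.67e-04, and adjusted p = 0.437 with an estimated correlation), with 0 of 18 passing over all genes and 7 falling adjusted over the list alone, and the call ended with the covariate for detected genes, at -0.66. Prkcd, a thalamic protein kinase, was at 8.78 ± 3.97 against 43.9 ± 41.6 CPM, with 91.9, 19.4 and 20.3 CPM in the control libraries, and its log2 change of -2.32 was -1.18 without control replicate 1. Synaptic genes had a median of -0.29 (adjusted p = 0.00619, and adjusted p = 0.521 with an estimated correlation), with Gad2, an enzyme of GABA synthesis, at 184 ± 25.5 against 331 ± 82.8 CPM and 0 of 41 passing over all genes or adjusted over the list alone. The synaptic call ended without diabetes replicate 4, at -0.25, and with the length correction, at -0.19. Blood cell genes had a median of 1.78 (adjusted p = 0.00110, and adjusted p = 0.437 with an estimated correlation), with 0 of 8 passing over all genes, 4 globins rising adjusted over the list alone and Hba-a2 at 205 ± 201 against 37.2 ± 9.75 CPM, the diabetes libraries being at 77.0, 148, 91.9 and 503 CPM in replicates 1 to 4. Without the low-count filter, which adds members, the blood median was -0.04. The blood score was 2.85 in diabetes replicate 4 and -0.41 in diabetes replicate 1, and the thalamus and habenula score was 0.63 ± 0.42 in control and -0.50 ± 0.18 in diabetes. In the same libraries the score of oxidative phosphorylation was -0.20 ± 0.05 and 0.59 ± 0.30, beside the lower number of detected genes in every diabetes library. With that number as a covariate the medians of oxidative phosphorylation, ribosomal protein, glucocorticoid-induced and blood cell genes were 1.64, 1.00, 1.01 and 3.30. With the length correction the ribosomal protein median was 0.27. Camera called 16 of the 31 lists in this comparison and 0 with an estimated correlation.

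By edgeR, 3137 genes had an unadjusted p under 0.05, and DESeq2 called 630 and limma-voom with library weights 1177. Groups did not overlap for 14.7% of genes, against 5.71% by chance. The edgeR count was 0 with the stricter filter, the length correction or the covariate for detected genes, and 1, not among the 4, without the 2 doubted libraries.

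**Figure D2:**
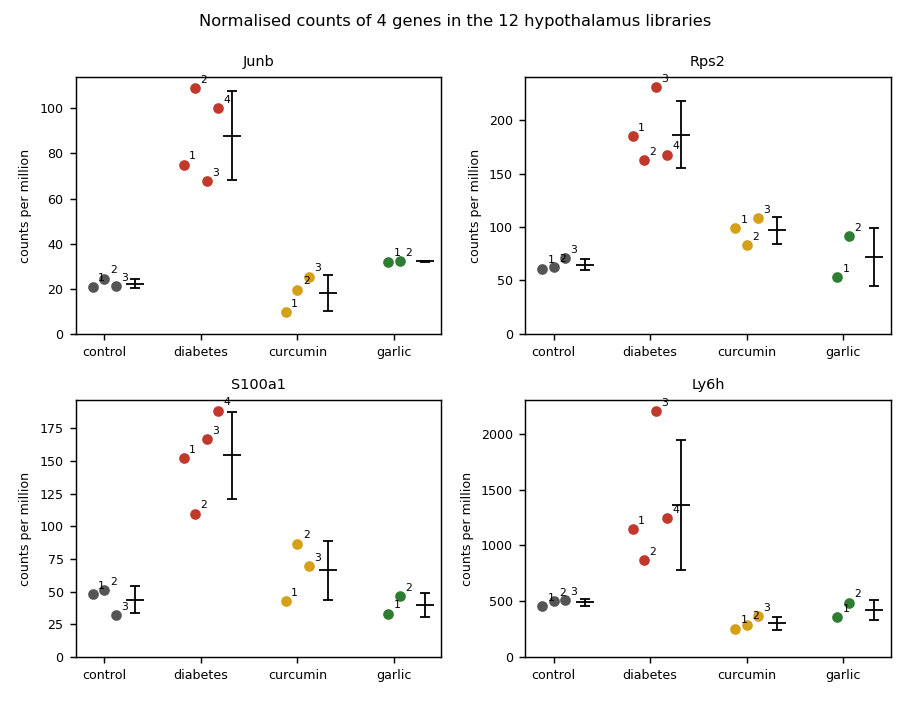
CPM of Junb, Rps2, S100a1 and Ly6h in each library, dots numbered by replicate, with group means and SD bars. Junb lay between 67.6 and 109 CPM in the diabetes libraries and between 20.8 and 24.4 in the control libraries.

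The comparison of curcumin with untreated diabetes asked what the compound changed in diabetic mice. By edgeR, 1 gene rose and 22 fell. At an unadjusted p under 0.05, 2672 were higher and 1715 lower. The balance of calls depended on the settings. It was 642 higher and 793 lower by DESeq2, 477 higher and 651 lower without the low-count filter and 754 higher and 1221 lower without curcumin replicate 2. It was 12 higher and 111 lower with RLE scaling, 8 higher and 115 lower by limma-voom, 6 higher and 59 lower with robust spread, 58 higher and 329 lower with the covariate for detected genes and 255 higher and 821 lower without the 2 doubted libraries. Junb fell by 2.27 ± 0.30 on the log2 scale (18.2 ± 8.00 against 87.9 ± 19.8 CPM, n = 3 and 4, adjusted p = 0.00862), and Ly6h fell by 2.17 ± 0.30 (303 ± 58.8 against 1364 ± 582 CPM, adjusted p = 0.00862). Tmsb10, which binds actin monomers, was at 70.2 ± 47.4 against 316 ± 75.5 CPM (log2 change -2.17 ± 0.41, adjusted p = 0.0460). Scand1, Fam183b, Lbhd2 and Nenf fell too, with log2 changes from -2.80 to -1.94. Bex1, Pfdn5, Tmem158, Tppp3 and Rps4l, named after their values were seen, also fell, and 8 further falling genes were ribosomal pseudogenes or unnamed gene models. Leaving out 1 library, the count was 1, 1975 and 9 without curcumin replicate 1, 2 and 3, and 2, 60, 2 and 3 without diabetes replicate 1 to 4. Junb passed in each of these 7 fits and Ly6h in each except that without curcumin replicate 1.

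Foxd2, a forkhead transcription factor, had 1 count over the 3 curcumin libraries and 390 over the diabetes libraries, a ratio of diabetes to curcumin of 312 (95% counting interval 55.6 to 12340, adjusted p = 0.0452). Tal1, a transcription factor of blood and some neurons, had 0 counts in every diabetes library and rose at least 252-fold (adjusted p = 0.0452), although its counts were 28, 556 and 12 in curcumin replicates 1 to 3 and control libraries had 20 to 53. Without curcumin replicate 2 that bound was 24.6-fold. The calls of both ended without curcumin replicate 1 or diabetes replicate 1, 3 or 4, and that of Foxd2 also without curcumin replicate 3, with adjusted p values of 0.0804 to 0.171 for Tal1 and 0.0828 to 0.149 for Foxd2.

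Oxidative phosphorylation genes had a median log2 change of -1.03 (adjusted p = 1.04e-21, and adjusted p = 0.579 with an estimated correlation), with 0 passing over all genes and 39 of 75 falling adjusted over the list alone. Without curcumin replicate 1 the median was -0.60, and with the length correction -0.62. The score of this list was -0.34 ± 0.83 with curcumin and 0.59 ± 0.30 in diabetes, beside 20917 to 29126 and 20133 to 22515 genes expected at the lowest depth. By library the score was -1.15, 0.51 and -0.39 in curcumin replicates 1 to 3. Replicate 2 thus lay within the diabetes range of 0.20 to 0.85. Ribosomal protein genes had a median of -0.97 (adjusted p = 8.65e-21, and adjusted p = 0.579 with an estimated correlation), with 0 over all genes and 30 falling adjusted over the list alone, among them Rplp1 (197 ± 96.6 against 647 ± 204 CPM). Immediate early genes had a median of -0.91, or -0.51 over edgeR log2 changes (adjusted p = 1.07e-07, and adjusted p = 0.178 with an estimated correlation). Junb fell over all genes and 7 members adjusted over the list alone, Fos having a log2 change of -1.59 ± 0.36, and without diabetes replicate 4 the median was -0.54. Endothelial and mural genes had a median of 1.14 (adjusted p = 0.00100, and adjusted p = 0.579 with an estimated correlation), with Flt1, a receptor of vascular growth factor, at 49.6 ± 24.2 against 13.5 ± 7.75 CPM and 3 members rising adjusted over the list alone and 0 over all genes. Without curcumin replicate 2 that list's call ended, at a median of 0.91, and with the covariate, at 0.66. Insulin and leptin signalling genes had a median of 0.40 (adjusted p = 0.00114, and adjusted p = 0.579 with an estimated correlation) and synaptic genes 0.40 (adjusted p = 0.00310, and adjusted p = 0.579 with an estimated correlation), each with 0 members over all genes and 1 rising adjusted over the list alone. The signalling and synaptic calls ended without curcumin replicate 1, at medians of 0.22 and 0.26, and with the length correction, at 0.19 and 0.13.

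Hypothalamic transcription factors had a median of -1.98, or -0.81 over edgeR log2 changes (adjusted p = 2.68e-06, and adjusted p = 0.579 with an estimated correlation), and neuroendocrine peptides -0.80 (adjusted p = 4.31e-07, and adjusted p = 0.579 with an estimated correlation), with 0 members of either passing over all genes and 2 and 9 falling adjusted over the list alone. The score of the transcription factors was -5.01 in curcumin replicate 2, against 0.11 or more in every other library. Without that library the transcription factor call ended, at a median of -0.36, as it did without the 2 doubted libraries, at -0.41, and with the covariate for detected genes, at -0.67. The peptide median was -0.36 without curcumin replicate 2 and -0.50 without the 2 doubted libraries. Avp, the antidiuretic hormone, was at 48.8, 0.348 and 336 CPM in the curcumin libraries and 1199 ± 575 in diabetes (log2 change -3.22, adjusted p = 0.157), a change of -2.60 without curcumin replicate 2, where it passed (adjusted p = 0.0285), and of -5.60 without curcumin replicate 3. Pomc stood at 40.2 ± 35.6 against 460.2 ± 425 CPM (log2 change -3.52, adjusted p = 0.0864), a change of -2.64 without diabetes replicate 4, where Pomc was highest at 1089 CPM, and of -4.34 without curcumin replicate 3. It passed without curcumin replicate 2, at -2.94 (adjusted p = 0.0283). Markers of pituitary and blood, high in diabetes replicate 4, had medians of -2.12, or -3.45 over edgeR log2 changes (adjusted p = 0.0184, and adjusted p = 0.579 with an estimated correlation), and -1.17 (adjusted p = 0.0126, and adjusted p = 0.579 with an estimated correlation), with 0 members over all genes and 1, Cga, and 0 falling adjusted over the list alone. Both calls ended without diabetes replicate 4, at -1.16 and -0.76. The pituitary call also ended without diabetes replicate 2 (-2.05) or curcumin replicate 2 (-2.58), with the stricter filter (-1.52), with the covariate (-2.45) or without the 2 doubted libraries (-0.90). The blood call ended without curcumin replicate 3 (-0.82), and the blood median was -1.80 without curcumin replicate 2 and -0.71 with the length correction. Without the low-count filter the pituitary median was -0.74. Camera called 14 of the 31 lists in this comparison and 0 with an estimated correlation.

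By edgeR, 4387 genes had an unadjusted p under 0.05, and DESeq2 called 1435 and limma-voom with library weights 123. Groups did not overlap for 9.62% of genes, against 5.71% by chance. All 23 genes were among the 1975 called without curcumin replicate 2, as were Avp, Pomc, Flt1, Fos and Rplp1, of which Fos also passed without curcumin replicate 3 (adjusted p = 0.0399) and Rplp1 without diabetes replicate 2 (adjusted p = 0.0465). By edgeR 1076 genes were called without the 2 doubted libraries, 2 with the stricter filter and 0 with only the 2 groups fitted (2395 at an unadjusted p under 0.05).

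**Figure D3:**
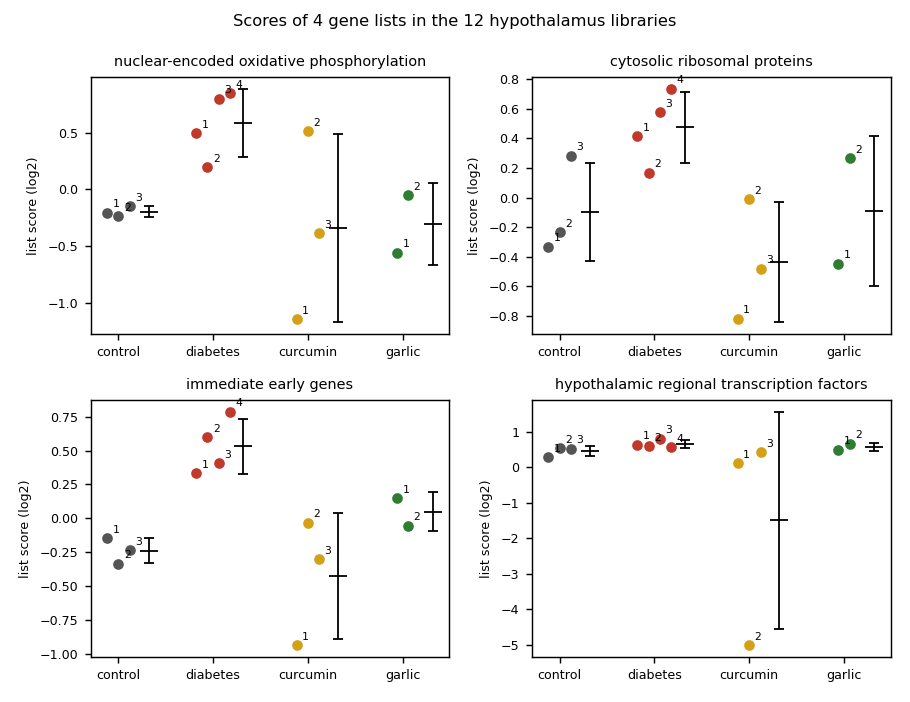
Scores of oxidative phosphorylation, ribosomal protein, immediate early and hypothalamic transcription factor genes in each library, as median deviations of log2 CPM. Curcumin replicate 2 lies at -5.01 for the hypothalamic transcription factors, and every other library at 0.11 or above.

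The comparison of aged garlic extract with untreated diabetes asked the same of the extract, with 2 libraries against 4. No gene passed the test by edgeR, with 2796 at an unadjusted p under 0.05 while DESeq2 called 487 and limma-voom with library weights 429. The smallest adjusted p, 0.0892, was shared by S100a1 and the ribosomal pseudogenes Rpl34-ps1, Rpl35a-ps6 and Rps10-ps2, which were named after their values were seen. S100a1 was at 39.6 ± 9.48 against 154 ± 33.4 CPM (log2 change -1.96 ± 0.33). Ly6h was at 419 ± 91.3 against 1364 ± 582 CPM, Ndufs8, a subunit of complex I, at 65.8 ± 9.40 against 212 ± 52.9 CPM, Rps2 at 72.2 ± 27.2 against 186 ± 31.1 CPM and Endog, a mitochondrial nuclease, at 12.1 ± 2.78 against 60.4 ± 22.2 CPM. Bola2, Grcc10, Tm2d3, Rps4l and Rex1bd completed the 10 of smallest p with pseudogenes and unnamed models left out, all lower with garlic in both libraries and with adjusted p values up to 0.12.

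Oxidative phosphorylation genes had a median of -0.91 (adjusted p = 1.03e-28, and adjusted p = 0.429 with an estimated correlation), with 0 over all genes and 28 of 75 falling adjusted over the list alone. Ribosomal protein genes had a median of -0.42 (adjusted p = 1.01e-13, and adjusted p = 0.429 with an estimated correlation), with 0 and 19. Without garlic replicate 1 that median was -0.09 and without garlic replicate 2 -0.92. Immediate early genes had a median of -0.44 (adjusted p = 6.47e-05, and adjusted p = 0.429 with an estimated correlation), with Junb (32.1 ± 0.133 against 87.9 ± 19.8 CPM) the 1 member falling adjusted over the list alone and 0 over all genes. Glucocorticoid-induced genes had a median of -0.41 (adjusted p = 2.92e-04, and adjusted p = 0.429 with an estimated correlation), with 0 over all genes, 2 (Mt1 and Cebpd) falling adjusted over the list alone and Mt1, a metallothionein, at 203 ± 27.3 against 517 ± 67.4 CPM, and the call ended without garlic replicate 2, at -0.22. Without garlic replicate 1 that median was -0.77. Synaptic genes had a median of 0.39 (adjusted p = 0.0169, and adjusted p = 0.643 with an estimated correlation), with 3 rising adjusted over the list alone, 0 over all genes and Nrxn3, an adhesion protein of synapses, at 207 ± 21.2 against 102 ± 12.0 CPM. The synaptic call ended without garlic replicate 1 or diabetes replicate 4, at medians of 0.15 and 0.31, and the median was 0.59 without garlic replicate 2. The synaptic call also ended with the length correction, at 0.11, without the low-count filter, at 0.44, and without the 2 doubted libraries, at 0.34. Beside these list changes, the garlic libraries had 33125 to 34719 genes expected at the lowest depth against 20133 to 22515 in diabetes. The score of oxidative phosphorylation was -0.30 ± 0.36 with garlic and 0.59 ± 0.30 in diabetes. With detected genes as a covariate the medians of oxidative phosphorylation, ribosomal protein, immediate early and glucocorticoid-induced genes were -2.18, -1.08, -0.71 and -0.75. With the length correction those of oxidative phosphorylation and ribosomal protein genes were -0.54 and -0.13.

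Cortex, hippocampus and striatum genes had a median of 0.97 (adjusted p = 0.0396, and adjusted p = 0.429 with an estimated correlation), with 0 of 19 passing over all genes or adjusted over the list alone and a score of 0.96 in garlic replicate 1 and 0.04 in replicate 2. The call ended without garlic replicate 1 (0.28) or diabetes replicate 2 (0.93) and without the low-count filter (1.02), and the median was 1.62 without garlic replicate 2. Blood cell genes had a median of -1.84, or -1.99 with zero-count groups at their bound (adjusted p = 4.59e-04, and adjusted p = 0.429 with an estimated correlation), with 4 globins falling adjusted over the list alone and 0 over all genes, and Hba-a2 stood at 40.7 ± 6.66 against 205 ± 201 CPM, a log2 change of -2.33 that was -1.38 without diabetes replicate 4. The blood median was -0.82 without the low-count filter and -3.87 with the covariate. Groups did not overlap for 20.8% of genes, against 13.3% by chance. The edgeR count was 2 without garlic replicate 1, 52 without garlic replicate 2, with S100a1 and Rps2 among them and the lone library left assumed to vary like the other groups, 1 without diabetes replicate 4 and 1 without the 2 doubted libraries. Camera called 15 of the 31 lists and 0 with an estimated correlation.

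Whether treatment moved genes against the diabetes change was asked across all 25562 genes, which are not independent replicates. The log2 changes of diabetes against control and of curcumin against diabetes correlated at r = -0.712 (covariance -2.40), where unchanged groups sharing the diabetes libraries gave -0.426 (covariance -1.0), a covariance difference of -1.39. For garlic, r was -0.849 (covariance -2.47) against -0.373 (covariance -1.01), a difference of -1.46. With the diabetes libraries split 2 and 2, r averaged -0.112 for curcumin (covariance -0.644) and -0.137 for garlic (covariance -0.725). The curcumin and garlic changes correlated at 0.699 (covariance 2.34), with 0.373 (covariance 1.01) for unchanged groups, a difference of 1.33, and 0.104 (covariance 0.598) with split libraries. Junb was the 1 gene called up in diabetes and down with curcumin, where independent lists would share 0.00344, and part of any excess may come from the shared diabetes libraries. The simulated r for curcumin ran only from -0.448 to -0.416, a range that need not cover differences shared by many genes of a library. The split covariances of -0.644 and -0.725 were smaller in size than the covariance differences of -1.39 and -1.46. The same held for the similarity, at 0.598 and 1.33. Those differences may therefore overstate the opposition and the similarity, although each split contrast has fewer diabetes libraries. Detected genes also differed, at 20133 to 22515 in diabetes, 25766 to 33157 in control, 20917 to 29126 in curcumin and 33125 to 34719 in garlic. No covariate for them was fitted to the correlations, so such a difference between libraries cannot be told apart from a treatment effect.

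Treated groups were also set against control. No gene passed for curcumin against control by edgeR, with 597 at an unadjusted p under 0.05, and DESeq2 called 10 and limma-voom with library weights 0. Chance alone would put 1278 genes under that p, more than were found. The p-values of this contrast therefore ran high, and the lack of calls does not show that these groups are alike. Ushbp1 (14.8 ± 5.25 against 3.85 ± 1.55 CPM), Mtus2 (60.4 ± 8.39 against 30.8 ± 3.93 CPM) and Tie1, an endothelial receptor (16.0 ± 5.83 against 4.95 ± 0.591 CPM), had the smallest p among higher genes, and Foxd2 and Nts, the neurotensin precursor (10.5 ± 6.04 against 33.5 ± 6.37 CPM), were among the lower genes of smallest p, all with an adjusted p of 1. Endothelial and mural genes had a median of 1.06 (adjusted p = 3.72e-13, and adjusted p = 0.768 with an estimated correlation), with 0 of 25 passing over all genes or adjusted over the list alone. The count of genes was 49 without curcumin replicate 2, all lower and Foxd2 among them, and 16 without the 2 doubted libraries. Groups did not overlap for 8.65% of genes, against 10% by chance.

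For garlic against control no gene passed by edgeR, with 28 at an unadjusted p under 0.05, while DESeq2 called 0 and limma-voom with library weights 0. Here too chance would put 1278 genes under that p, more than were found. The p-values ran high here as well, and the lack of calls does not show that garlic and control are alike. Slco1a4, a transporter of the blood-brain barrier, stood at 46.4 ± 11.5 against 15.6 ± 4.07 CPM and Ddn, a dendritic protein, had a log2 change of 1.15 ± 0.39, which was -0.20 without garlic replicate 1. Synpo2, Prkcd and Ntng1 were the lower genes of smallest p, and all 5 had an adjusted p of 1. Prkcd was at 15.0 ± 3.00 against 43.9 ± 41.6 CPM, a log2 change of -1.55 that was -0.40 without control replicate 1, where it was highest at 91.9 CPM. Thalamus and habenula markers had a median of -0.51 (adjusted p = 4.71e-05, and adjusted p = 0.711 with an estimated correlation), with 0 passing over all genes or adjusted over the list alone, and the call ended without control replicate 1, at -0.28, while the median was -1.05 with the covariate for detected genes. Groups did not overlap for 12.8% of genes, against 20% by chance.

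Curcumin against garlic tested the difference between the treatments directly. No gene passed by edgeR, with 408 at an unadjusted p under 0.05, and DESeq2 called 6 and limma-voom with library weights 0. As chance would put 1278 genes under that p, more than were found, these p-values ran high too. The lack of calls does not show that the treatments act alike. Slc5a7, the choline transporter of cholinergic neurons, was at 0.0661 ± 0.0573 against 7.62 ± 6.76 CPM (adjusted p = 0.711), with 12.4 and 2.84 CPM in the garlic libraries, and Foxd2 at 0.0166 ± 0.0287 against 2.45 ± 1.98 CPM (adjusted p = 0.711). Ddn was at 23.5 ± 1.25 against 89.0 ± 76.2 CPM, with 143 and 35.1 CPM in the garlic libraries, and its log2 change of -1.92 was -0.56 without garlic replicate 1 and -2.61 without garlic replicate 2, where it passed (adjusted p = 2.50e-04) with replicate 1 as the lone garlic library and the spread taken from the other groups. With unnamed models left out, Mtus2 (60.4 ± 8.39 against 30.2 ± 8.75 CPM), Sema3f and Cacng5 had the smallest p among higher genes. Hypothalamic transcription factors, whose score was -5.01 in curcumin replicate 2, had a median of -1.89, or -0.49 over edgeR log2 changes (adjusted p = 0.00225, and adjusted p = 0.783 with an estimated correlation), with 3 falling adjusted over the list alone and 0 over all genes. Without that library the direction of the test turned, at a median of 0.00280, and the median was -2.93 without curcumin replicate 3, while the call ended without garlic replicate 1, at -1.99, and without the low-count filter, at -1.92, and the median was -5.04 with the covariate for detected genes. The count of genes was 18 without curcumin replicate 2, 2 without garlic replicate 1, 1 without garlic replicate 2 and 1 without the 2 doubted libraries, and 14.1% of genes did not overlap, against 20% by chance.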

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

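The tests of another brain region and of a curcumin effect in every animal were chosen after the result was seen. Among the 4 diabetes libraries, 7 of 141 values had a library whose gap to its nearest neighbour took a share of the group's range above the 95% critical value of Dixon's test, where chance gives 7.05, and 6 of the 7 were in replicate 4. Gh, growth hormone, took 1 of the range, with 732 CPM in diabetes replicate 4 and 0 in the other 3. Prl, prolactin, took 1, with 97.4 CPM in that library and 0 in the others, and Cga, a pituitary hormone subunit, took 0.913, with 19.4 CPM. The globin genes Hbb-bs and Hba-a2 took 0.878 and 0.833, at 528 and 503 CPM in replicate 4 and group medians of 132 and 120.1. Dlx2, a transcription factor, took 0.865, being lowest in replicate 4 at 8.99 CPM. Penk, the enkephalin precursor, took 0.840, being lowest in replicate 2 at 133 CPM.

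Hypothalamic transcription factors were lower in curcumin than in diabetes, at a median log2 change of -1.98, or -0.81 over edgeR log2 changes. Whether curcumin had an effect in every treated animal stays open: the mean score of replicates 1 and 3 differed from the diabetes mean by -0.379, beyond the diabetes SD of 0.109, but the size of the group difference is set by replicate 2. Tissue from another brain region in 1 library may account for the pattern: the score of curcumin replicate 2 was -5.01 against 0.11 or more elsewhere, and the median without it was -0.361. In that library Lhx9 and Pou4f1, transcription factors on the thalamus and habenula list, stood at 84.7 and 18.9 CPM, against 4.83 and 0 in replicate 1 and 2.08 and 0 in replicate 3, but the score of the whole list was 0.24 and that of cortex, hippocampus and striatum -0.41, so no region is identified. A wrong label of that library stays open too.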

How the results depend on the processing

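The fits without 2 doubted libraries, with a length correction, with a covariate for detected genes and with rank-based camera were chosen after the data were seen. For diabetes against control the count was 6, all higher, with RLE scaling or robust spread, 468 without a filter, 342 with only the 2 groups fitted, 630 by DESeq2 and 1177 by limma-voom. It was 0 by edgeR with the stricter filter (2207 at an unadjusted p under 0.05), the length correction (2713) or the covariate (3336), 1 without the doubted libraries, and 0 to 1 leaving out each library. Curcumin against diabetes gave 123 with RLE, 1128 without a filter, 2 with the stricter filter, 65 with robust spread, 0 with only the 2 groups (2395 unadjusted), 1076 without the doubted libraries, 52 with the length correction, 387 with the covariate, 1435 by DESeq2, 123 by limma-voom and 1 to 1975 leaving out each library. Garlic against diabetes gave 356 without a filter, 4 with robust spread, 1 without the doubted libraries, 1 with the length correction, 487 by DESeq2, 429 by limma-voom and 0 to 52 leaving out each library. Curcumin against control gave 43 without a filter, 16 without the doubted libraries, 10 by DESeq2 and 0 to 49 leaving out each library. Garlic against control gave 3 without a filter. Curcumin against garlic gave 45 without a filter, 1 without the doubted libraries, 6 by DESeq2 and 0 to 18 leaving out each library. The stricter filter tests fewer genes and the left-out fits hold fewer libraries. For garlic against diabetes, leaving out garlic replicate 1 or 2 raised the genes tested to 31107 and 30759. There DESeq2 adjusted over 12229 genes, and the fit of only the 2 groups tested 22148. Otherwise the cause was not tested.

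Replicate numbers were fitted as a replicate block although the labels name no litter or batch. Same-number pairs correlated from -0.308 to 0.528, 7 of 15 above 0.1 (mean 0.0708, other pairs -0.0284), and 6 of 12 libraries correlated best with their own number, so the numbers were not taken to pair samples. Some libraries of different groups were closer than those of 1 group. Chi-square per degree of freedom was 23.0 for control 1 with garlic 1 and 28.6 for control 3 with garlic 2. It was 58.8 for control 1 with control 3 and 68.4 between the garlic libraries. The cause was not tested. The replicate block called 1, 47 and 1 genes for the 3 main comparisons, of which 0 were among the 4 and 22 among the 23 called without it, and 10 lists for diabetes against control and 4 for garlic against control. It turned Gh to 7.76 with curcumin and 10.27 with garlic, Prl to 8.36 and Npy to 0.15 with garlic. Diabetes replicate 4 is the only library of its number, and the other diabetes libraries had 0 counts of Gh and Prl. The values of these 2 genes are therefore no bound.

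Of 16, 14, 15, 13, 8 and 11 lists called in the 6 comparisons, camera with an estimated correlation called 0 in each, at smallest adjusted p values of 0.0836, 0.178, 0.429, 0.768, 0.711 and 0.783, with 2, 2, 1, 1, 2 and 0 at an unadjusted p under 0.05. Fry, which asks whether a list moves 1 way on balance, called 0 except 1 for curcumin against diabetes, the immediate early genes. The count was 9 with the covariate for curcumin against diabetes, 8 without the doubted libraries for curcumin against control, 3 without a filter for garlic against control and 7 without a filter or without the doubted libraries for curcumin against garlic. Leaving out each library gave 9 to 14 for curcumin against diabetes, 7 to 13 for curcumin against control, 2 to 14 for garlic against control and 5 to 15 for curcumin against garlic. The covariate turned the peptide median to -0.70 for diabetes against control and to 0.99 for garlic against diabetes, and the hypothalamic transcription factors to 3.82 for garlic. Tanycyte and ependymal genes, at a median of -0.37 with curcumin, or -0.18 over edgeR log2 changes, turned to 0.63 with curcumin without the doubted libraries and ran from -0.83 to 0.44 leaving out each library. Hypothalamic transcription factors in curcumin against garlic turned to 0.0277 without the doubted libraries and ran from -2.93 to 0.00280.

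With the covariate, log2 changes for diabetes against control turned in Serpina3n (-0.85), Nkx2-4 (-3.52), Avp (-1.18), Npy (1.97), Pmch (-2.85) and Hcrt (-4.50). For garlic against diabetes they turned in Cartpt (0.38), Pomc (0.36), Serpina3n (1.73), Rora (-0.87), Oxt (2.56), Avp (1.99), Pmch (4.42) and Hcrt (6.66). Without the doubted libraries Gh became 9.41 with curcumin and 7.89 with garlic, and Prl 5.70 with garlic, while limma-voom gave Gh 0.72 and 1.49. The diabetes libraries left without replicate 4 had 0 counts of Gh and Prl, so the first 3 values depend on the prior count and are no bound. Leaving out each library, Gh ran from -12.56 to 8.82 with curcumin and -7.45 to 7.88 with garlic, Prl from -11.94 to 5.70 with garlic, Lepr from -0.47 to 1.57 with curcumin, Npy from -0.57 to 0.88 and Gfap from -0.14 to 0.67 in diabetes, and Ddn from -0.20 to 1.84 for garlic against control. At the upper ends of Gh and Prl the diabetes group had 0 counts, as did the lone garlic library at the lower end of Prl. Those ends depend on the prior count and are no bound. None of these genes passed the test in the comparison concerned. Apart from the left-out libraries themselves, the cause was not tested.

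The correlation of diabetes and curcumin changes was -0.599 by Spearman, -0.559 without the doubted libraries, -0.112 with split diabetes libraries and -0.804 to -0.515 leaving out each library. For garlic it was -0.137 split and -0.899 to -0.669. The similarity of both treatments was 0.583 by Spearman, 0.551 without the doubted libraries, 0.104 split and 0.503 to 0.793. In the split fits the shared libraries no longer enter both contrasts, and each contrast has fewer of them. At these depths, genes with 3 counts in a library stand at 0.0991 to 0.232 CPM, and differences between levels both near it were not detectable at this depth. With prior count 5 the 3 correlations were -0.640, -0.819 and 0.618. Of 182 gene values, 177 kept their direction and side of the threshold with RLE and 174 with robust spread, while 71 newly passed by DESeq2 and 91 without a filter. Of 48 list medians, 46 kept both with RLE, 46 with rank-based camera, 45 without a filter, 40 with the stricter filter, 38 with the length correction, 36 with the block and 30 with the covariate, and 256 of 316 did so leaving out each library.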

Other observations

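The tests of the number of detected genes and of pituitary and blood in 1 library were chosen after the result was seen. So was a margin of 1 standard error of the list-score difference, applied to every test of a median. Further gene lists were called by camera in diabetes against control, which ranks a list against the other genes, while fry, which asks whether a list moves 1 way on balance, called 0 lists there. Antioxidant genes had a median log2 change of 0.37 (camera adjusted p = 3.72e-04, adjusted p = 0.437 with an estimated correlation), heat shock proteins 0.24 (camera adjusted p = 0.00713, adjusted p = 0.437 with an estimated correlation) and genes of the unfolded protein response 0.12 (camera adjusted p = 0.0206, adjusted p = 0.437 with an estimated correlation), with 0 members of each passing over all genes or adjusted over the list alone. Astrocyte genes had a median of 0.42 (camera adjusted p = 1.01e-04, adjusted p = 0.437 with an estimated correlation), whose call ended without control replicate 3, at 0.00, and which was 0.63 without control replicate 1 and 0.64 without control replicate 2. The interferon list had a median of 0.36 (camera adjusted p = 0.00191, adjusted p = 0.510 with an estimated correlation) but a mean of -0.03, with 0 members over all genes and 2, H2-D1 and H2-K1, rising adjusted over the list alone. Its call ended without diabetes replicate 4, at 0.08, and its median was 0.63 without diabetes replicate 3. Neuroendocrine peptides had a median of 0.12 (camera adjusted p = 0.0232, adjusted p = 0.586 with an estimated correlation), and cholesterol, fatty acid and glycolysis genes had medians of 0.06, 0.01 and 0.11, each at a camera adjusted p of 0.0367 (adjusted p = 0.437, 0.586 and 0.619 with an estimated correlation). Over edgeR log2 changes the medians were 0.57 for interferon, 0.29 for peptide and -0.02 for fatty acid genes, the last of opposite sign. With the covariate for detected genes the calls of heat shock, unfolded protein response, cholesterol and fatty acid genes ended, and that of the peptides turned, at -0.70. The calls of heat shock and glycolysis genes ended with the length correction, those of peptide, cholesterol, fatty acid and glycolysis genes with the stricter filter, and those of interferon, fatty acid and glycolysis genes without the 2 doubted libraries. Each of the calls above except that of the antioxidant genes ended when 1 library was left out. The heat shock call ended without diabetes replicate 1 (0.14), and its median moved by over 1.5 times without control replicate 3 (0.09). The unfolded protein response call ended without control replicate 3 (0.05), diabetes replicate 1 (0.06) or diabetes replicate 3 (0.10). The peptide call ended without control replicate 3 (-0.06) or diabetes replicate 2 (0.01), and its median moved by over 1.5 times without control replicate 2 (0.06), diabetes replicate 1 (0.38) or diabetes replicate 4 (-0.04). The cholesterol call ended without control replicate 3 (0.01), diabetes replicate 1 (0.04) or diabetes replicate 3 (0.04), and its median moved by over 1.5 times without control replicate 1 (0.14) or diabetes replicate 2 (0.09). The fatty acid call ended without control replicate 3 (-0.12), diabetes replicate 1 (-0.02), diabetes replicate 3 (0.07) or diabetes replicate 4 (0.03), and its median moved by over 1.5 times without control replicate 1 (0.10), control replicate 2 (0.04) or diabetes replicate 2 (0.08). The glycolysis call ended without control replicate 3 (0.02), diabetes replicate 1 (0.11), diabetes replicate 3 (0.07) or diabetes replicate 4 (0.04), and its median moved by over 1.5 times without control replicate 1 (0.04) or control replicate 2 (0.00).

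The other 15 lists were not called in diabetes against control, with camera adjusted p values from 0.0540 to 0.913. Their median log2 changes were -0.12 for appetite genes, -0.32 for insulin and leptin signalling, -0.12 for microglia, -0.41 for the inflammatory response, -0.05 for oligodendrocytes and -0.11 for their precursors. They were -0.33 for tanycytes and ependyma, 0.02 for endothelial and mural cells, -0.41 for choroid plexus, -0.28 for meninges, 0.67 for pituitary and -0.22 for cortex, hippocampus and striatum. The pituitary score was 4.57 in diabetes replicate 4, against a diabetes group median of 0.384. Cga was at least 112-fold higher in diabetes, or at least 12.0-fold without diabetes replicate 4. Its levels were 0, 1.69, 0 and 19.4 CPM in diabetes replicates 1 to 4. The bound without replicate 4 therefore rests on replicate 2 alone, and no rise across the group is shown. 0 members of these lists passed over all genes, and adjusted over the list alone 2 rose in the appetite list, 2 (Cga and Pitx1) in the pituitary list and 1 clock gene, Rora, fell. Hypothalamic transcription factors had 0.10, mitochondrially encoded genes -0.25 and clock genes -0.14. Over edgeR log2 changes the medians of these lists were 0.14 for microglia, -0.03 for the inflammatory response, -0.02 for tanycytes, 0.41 for endothelial and mural cells, -0.00429 for choroid plexus, 0.80 for meninges, 3.73 for pituitary, -0.12 for cortex, hippocampus and striatum and 0.16 for hypothalamic transcription factors, with the sign turned for microglia and meninges. The median or mean differed in sign from the test for appetite, microglia, oligodendrocyte, precursor, tanycyte and meningeal genes.

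Oxidative phosphorylation, ribosomal protein and immediate early genes stood higher in diabetes than in control, and shorter transcripts did too, with a Spearman correlation across 13653 genes outside the lists of -0.432. Transcript length bias as the whole cause is argued against for oxidative phosphorylation and immediate early genes, whose medians after the length correction were 0.529 and 0.713 against bounds of 0.368 and 0.426, set at 50% of the uncorrected medians, with standard errors of 0.0980 and 0.115, but for ribosomal proteins the value of 0.271 exceeded its bound of 0.255 by only 0.0161, within a standard error of 0.208, so this explanation cannot be told apart there. Fewer genes detected in the library would predict, from the trend within groups, differences of -0.813 (95% interval -1.79 to 0.162) for oxidative phosphorylation and -0.532 (-1.04 to -0.0200) for immediate early genes. Both upper limits lie under 50% of the observed differences of 0.781 and 0.769, while the -0.333 for ribosomal proteins has an upper limit of 0.515. That trend leans on the curcumin group. There replicate 2, a doubted library, had 29126 genes and an oxidative phosphorylation score of 0.51, against 20917 and -1.15 in replicate 1. Among the diabetes libraries, replicate 2 had the most genes, 22515, and the lowest score, 0.20. The test therefore cannot decide, and this explanation stays open for each of these lists. Pituitary and blood in 1 library do not account for the immediate early genes, whose median was 0.647 without diabetes replicate 4, above its bound of 0.426. An effect of diabetes and the high-fat diet may contribute, and tissue makeup and RNA quality stay open beside it, since every diabetes library had fewer detected genes than every control library.

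Other splits of the same libraries were refitted. For diabetes against control, 1 of 35 splits, the real one, gave 4 genes, the highest other giving 1. That is the smallest share 35 splits can give, and it argues against chance for that count under these settings. It was 1 of several such tests, with no adjustment for their number. With the stricter filter, the length correction or the covariate, where edgeR called 0 genes, no splits were refitted. With 1 library left out none of the 4 genes passed, with fewer libraries in the fit, while the log2 changes of Junb, Rps2 and S100a1 ran from 1.87 to 2.10, 1.41 to 1.60 and 1.64 to 1.95. For its lists 4 of 35 splits gave 16 or more, the highest other 19, so chance cannot be excluded. For curcumin against diabetes 2 of 35 splits gave 23 genes or more, so chance cannot be excluded. The highest other gave 414, from a split that exchanged curcumin replicate 2 with diabetes replicate 2, which points to a structure of the samples that was not tested. The lists of that comparison gave 14 or more calls in 5 of 35 splits, the highest other 16, and chance cannot be excluded. For curcumin against control the 10 splits are too few for a share under 0.05: the real split gave 0 genes by edgeR (597 at an unadjusted p under 0.05, where chance gives 1278, 10 by DESeq2 and 0 by limma-voom), the highest other 1, and for lists the real split gave 13 and the highest other 16.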
